A study of Homo sapiens with 24 samples.

How the data were processed

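RNA sequencing libraries were made from PC9 cells in RPMI medium with or without asparagine, with 200 nM ISRIB or 0.004% DMSO, 6 or 24 h before a common endpoint, per the labels. The medium was removed, cells were rinsed and fresh medium was given at each start, so the 6 h and 24 h groups also differ in the age of their medium. The 24 libraries formed 8 groups of 3 biological replicates.

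The authors aligned and counted the reads with Bowtie2 and featureCounts against hg38 and used DESeq2, per the submitters' processing notes; versions, strandedness and the role of each tool were not given in the sources used here. The deposited table of counts held reads per gene for 37411 genes in each library. A second deposited table held log2 values after the variance-stabilizing transformation of DESeq2, with a floor of 3.45 where the count was 0 and a highest value of 18.6, and served as an alternative input. Of the 37411 identifiers 36620 matched GENCODE release 29 without regard to version, 32930 of them with the same version, and coordinates and gene types were taken from it.

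Counts were scaled with TMM factors (0.902 to 1.08) and filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 17409 genes and set aside 0.0751% to 0.0980% of the counts. A model with 1 mean per group was fitted to the 24 libraries, with 16 residual degrees of freedom and a common dispersion of 0.0176. Contrasts were tested with the quasi-likelihood F test of edgeR, and p was adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The 13 comparisons were asparagine withdrawal with vehicle or ISRIB and ISRIB against vehicle with or without asparagine at each time, the interaction of medium and drug at each time, the difference between 24 h and 6 h of the vehicle withdrawal response and of the ISRIB response without asparagine, and 24 h against 6 h in vehicle with asparagine. Fold changes are on the log2 scale with their SE, and CPM are means with the SD of 3 libraries.

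The genes named were set by a rule. The 12 stress-response genes were followed in every comparison. For withdrawal with vehicle and for ISRIB against vehicle, the 8 genes with the largest rise and the 8 with the largest fall were named among those with adjusted p below 0.05, a mean of at least 5 CPM over the 6 libraries and no overlap of CPM between the groups. For withdrawal with ISRIB and for time the rule named 5 each way, and for interactions and differences between times 5 each way without the condition on overlap. For a gene list it named up to 4 members with the smallest adjusted p and up to 2 with at least 5 CPM and the largest. Genes named outside the rule are stated as such. Some genes that the rule would name are not reported here.

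For the 24 gene lists, camera of limma 3.58.1 tested each list with its preset correlation between genes, and with an estimated correlation as an alternative, with adjustment over the 24 lists of a comparison. Calls were also counted with the p of the members adjusted over the list alone. The lists, the comparisons, the test, the naming rule and all alternatives were fixed before the data were examined, apart from the 3 alternatives on GC content and the 2 list tests on GC-corrected values, which were chosen after seeing the data.

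Alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter on low counts, a filter of 5 CPM in 3 libraries, a minimum of 2-fold, a fit to the groups compared alone, the replicate number as a block, limma on the deposited log2 values, and each library left out. Lists were also tested with fry, with the block and on the deposited log2 values. The GC correction fitted in each library a robust natural spline with 5 degrees of freedom of its log2 deviations on transcript GC content and removed it as an offset, which was known for 17326 genes (99.5% of those tested). It was also run with the replicate block, and the 3 libraries with the most negative slope on GC content were left out as another alternative, while 2 libraries with positive slopes larger in size than the smallest of these 3 were kept.

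Whether replicate numbers pair the libraries was checked from the correlation of deviations from group means. All 3 pairs were above 0.1 for withdrawal with vehicle at 6 h (0.304 to 0.339) and 24 h (0.187 to 0.350) and for ISRIB without asparagine at 6 h (0.327 to 0.470), and not for the other 6 comparisons of 2 groups. The labels do not say what the numbers mark, and 16 of 24 libraries correlated best with their own number. The first principal component of these deviations held 37.0% of their variance. Its gene weights correlated with GC content at 0.838 in size, so the GC trend can raise or lower the correlations of pairs.

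Sensitivity was tested on simulated data with 50 genes at each fold. Genes of all folds were changed in the same simulated set, and the libraries were drawn without a GC trend. With 17283 genes in the step, withdrawal with vehicle at 24 h gave 4, 24, 43 and 50 recovered genes at 1.25-, 1.5-, 2- and 4-fold. ISRIB with asparagine gave 3, 28, 38 and 49 at 6 h with 17311 genes, and 5, 27, 41 and 50 at 24 h with 17280 genes. Withdrawal with vehicle at 6 h gave 2, 21, 40 and 50 with 17269 genes. False calls numbered 8, 10, 4 and 10 in that order.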

Results

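PC9 is a human non-small cell lung cancer line. Its cells were moved to medium with or without asparagine, a non-essential amino acid that cells can make with the enzyme ASNS. Each medium carried either 200 nM ISRIB, a small molecule that activates the translation initiation factor eIF2B and so blunts the integrated stress response, or 0.004% DMSO as vehicle. RNA was collected 6 or 24 h after the change of medium. The 8 groups held 3 biological replicates each, per the series' design text, and the 24 libraries carried 16737384 to 27495861 gene-assigned reads. Between 22911 and 25642 genes had at least 1 count in a library, and 17409 genes were tested. Mitochondrially encoded genes took 6.19% to 8.95% of the counts, and the 10 most abundant genes took 6.83% to 9.46%.

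Libraries of the same group differed in how their counts followed the GC content of the transcript. The slope ran from -0.38 to 0.22 on the log2 scale per 10 points of GC. It was most negative in replicate 3 with ISRIB and asparagine at 24 h (-0.38), replicate 3 with ISRIB and no asparagine at 6 h (-0.35) and replicate 1 with ISRIB and asparagine at 6 h (-0.19). The largest positive slopes were 0.22 in replicate 2 with vehicle and asparagine at 6 h and 0.21 in replicate 1 with ISRIB and no asparagine at 24 h. Counts of changed genes without the 3 libraries of most negative slope are given where they moved by more than 1.5 times. None of the 3 is in the groups compared for withdrawal with vehicle or for ISRIB without asparagine at 24 h. The same holds for the vehicle difference between times and for time. Their omission moves these counts only through the filter, scaling and estimate of spread shared by all groups.

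**Figure D1:**
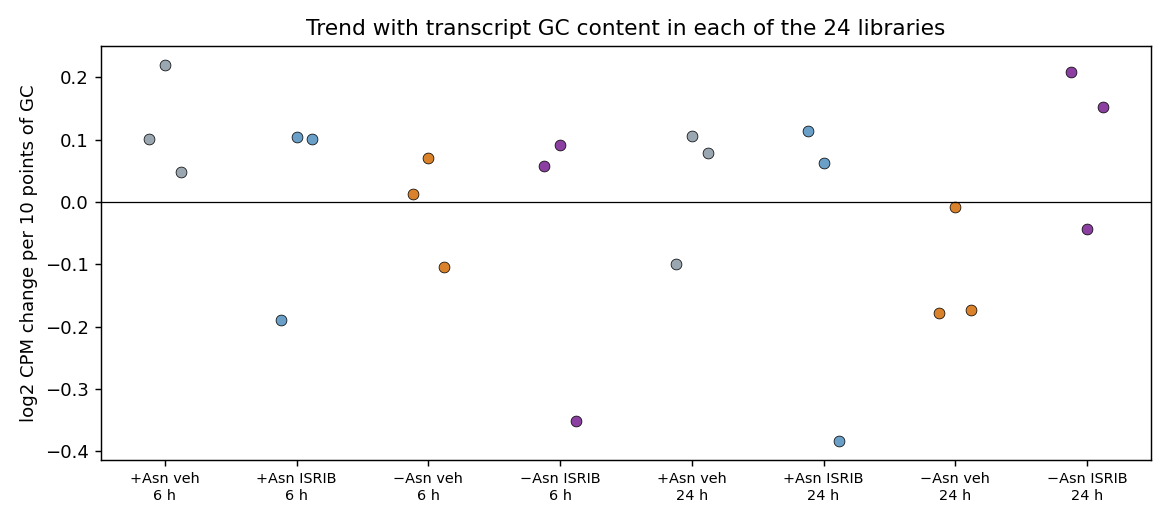
Slope of each library's log2 CPM on transcript GC content (vertical axis, log2 units per 10 points of GC) by group (horizontal axis), 1 point per library. The lowest points, at -0.38 and -0.35, are both replicate 3 of an ISRIB group.

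The genes followed in every comparison were 12 members or targets of the integrated stress response, placed here on GRCh38 by GENCODE release 29. ASNS (ENSG00000070669.16) lies on chromosome 7 from 97852118 to 97872542, and ATF4 (ENSG00000128272.14), which encodes the transcription factor at the centre of this response, on chromosome 22 from 39519695 to 39522685. ATF3 lies on chromosome 1 from 212565334 to 212620777, DDIT3, which encodes CHOP, on chromosome 12 from 57516588 to 57521737, and DDIT4, which encodes an inhibitor of mTORC1, on chromosome 10 from 72273920 to 72276036. TRIB3 lies on chromosome 20 from 362835 to 397559, CHAC1, which encodes a glutathione-degrading enzyme, on chromosome 15 from 40952962 to 40956519, and SESN2 on chromosome 1 from 28259527 to 28282491. PPP1R15A, which encodes GADD34, a regulatory subunit of an eIF2 alpha phosphatase, lies on chromosome 19 from 48872392 to 48876057. VLDLR lies on chromosome 9 from 2621834 to 2660053, STC2 on chromosome 5 from 173314713 to 173329503, and SLC7A11, which encodes the cystine transporter, on chromosome 4 from 138164097 to 138242349. Each was annotated as a protein-coding gene, and its value counted reads over the gene.

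**Figure D2:**
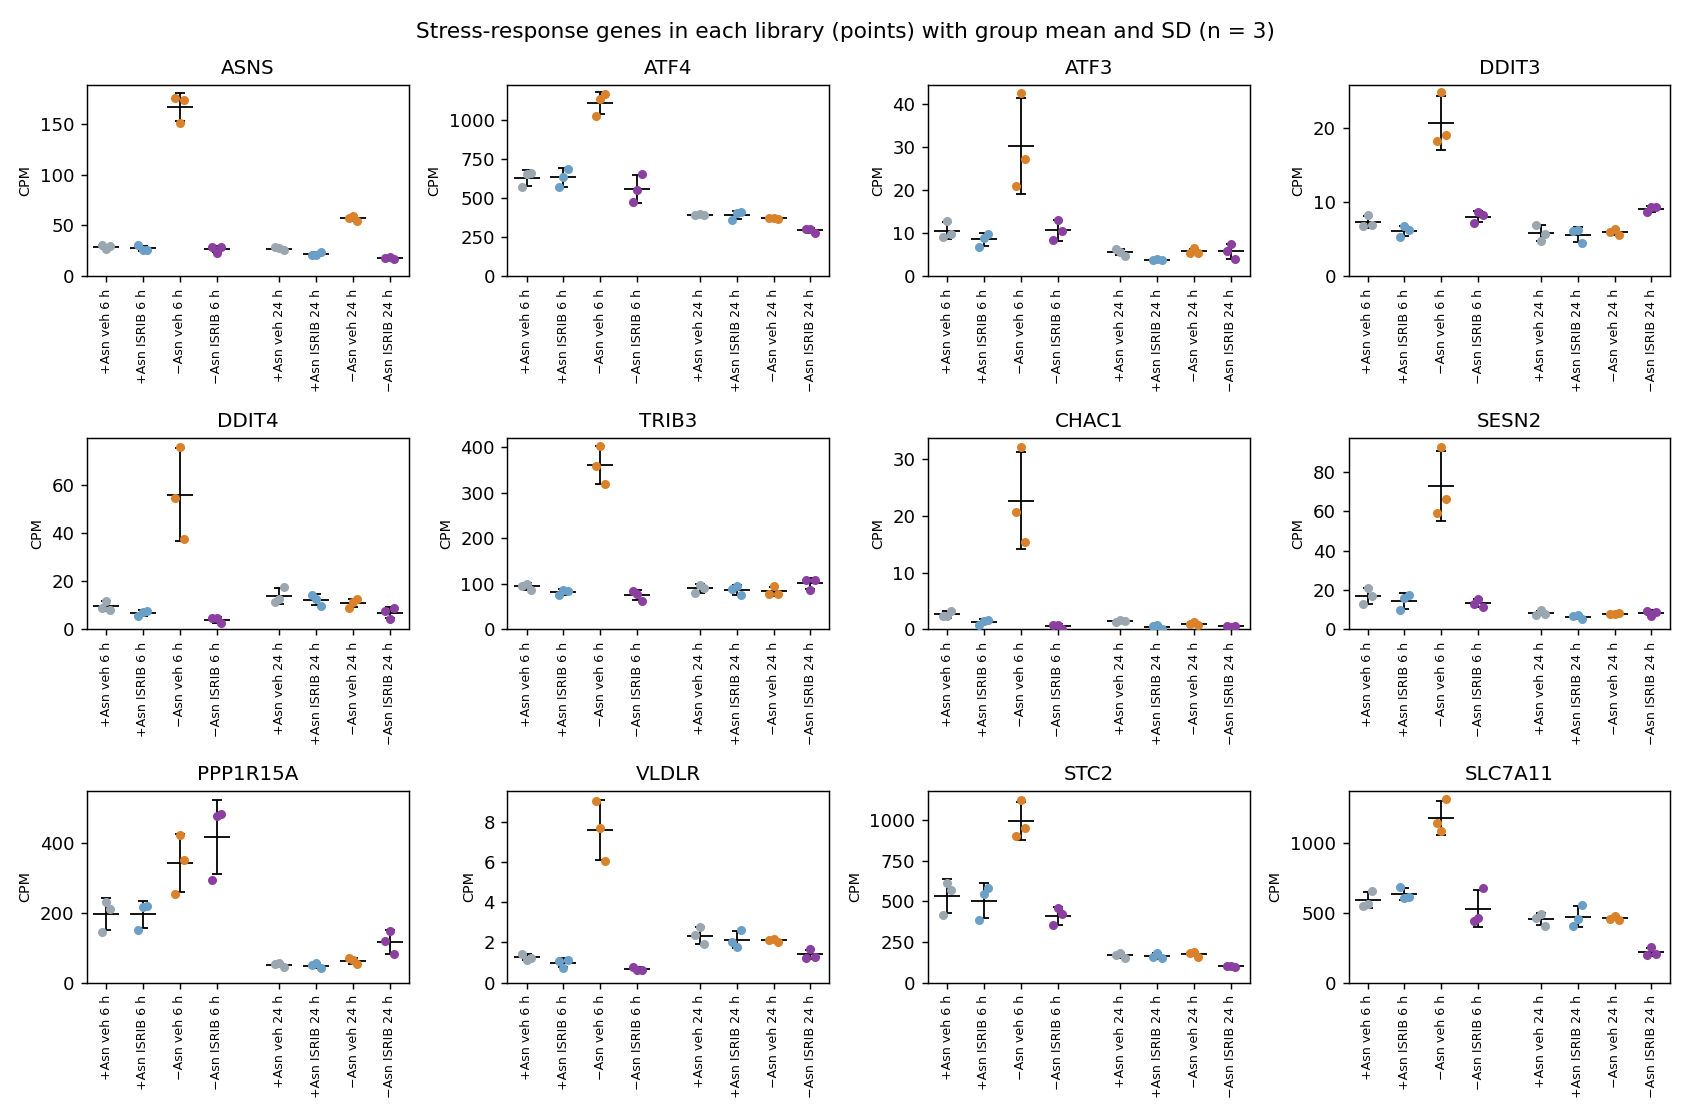
CPM (vertical axis, starting at 0) of 12 stress-response genes in each library, by group (horizontal axis); points are libraries, and the line and bars give the mean and SD of 3 libraries. ASNS averaged 166 CPM without asparagine with vehicle at 6 h, 57.1 CPM at 24 h, and at most 29.0 CPM in the other 6 groups.

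The first comparison asked what removing asparagine did in vehicle-treated cells. At 6 h ASNS rose from 29.0 ± 2.11 to 166 ± 13.6 CPM (SD, n = 3), a log2 change of 2.52 ± 0.10 (SE; adjusted p = 7.8e-13, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). ADM2, which encodes the peptide intermedin, rose by 3.52 ± 0.29, CHAC1 by 3.11 ± 0.37 and DDIT4 by 2.55 ± 0.27 on the log2 scale. TNFSF15, KIF21B, SESN2 and RNF144B completed the 8 largest rises among genes with at least 5 CPM and no overlap between the groups, at 2.16, 2.11, 2.11 and 2.01, and in the other comparisons of 2 groups the genes said to have moved most are also ranked within these limits. ATF4 rose from 627 ± 50.2 to 1107 ± 71.8 CPM, a log2 change of 0.82 ± 0.10. Of the other followed genes VLDLR rose by 2.58, TRIB3 by 1.94, ATF3 by 1.52, SLC7A11 by 1.00, STC2 by 0.90 and PPP1R15A by 0.81, and DDIT3 rose from 7.31 to 20.7 CPM. In all, 576 genes rose and 219 fell, and 171 of the first and 15 of the second changed at least 2-fold.

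The falls were smaller. EIF5, which encodes a translation initiation factor, fell by 1.18 ± 0.16 on the log2 scale and its pseudogene EIF5P1 fell by 1.16 ± 0.25; the copies can share reads, so neither value was certain. ACTBP7, an actin pseudogene with the same doubt, fell by 1.10. CNNM1 (-1.09), DUSP2 (-1.09), a MAP kinase phosphatase gene, PPARGC1B (-1.04), which encodes a transcriptional coactivator of mitochondrial genes, ZNF488 (-1.03) and TBC1D30 (-0.96) fell as well.

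Targets of ATF4 and CHOP rose almost as a group at 6 h with vehicle: 30 of 33 measured members rose, 1 fell and 2 did not pass, with the same 30 and 1 when adjusted over the list alone. TRIB3, VLDLR, ADM2 and CTH (1.95) had the smallest adjusted p, and CEBPB (0.23 ± 0.22) had the largest. The member that fell was ATF5, named after its values were seen. The list's camera test gave an adjusted p of 7.2e-44, and 5.9e-06 with an estimated correlation. Amino acid transporter genes rose in 7 of 16 cases (9 rose and 2 fell when adjusted over the list alone), among them SLC38A2 (1.44), SLC1A4 (1.74), SLC6A9 (1.66) and SLC7A1 (0.86), while SLC36A4 was at 0.08 ± 0.14. Aminoacyl-tRNA synthetase genes rose in 10 of 18 cases (11 rose and 1 fell when adjusted over the list alone), with GARS at 1.38, SARS at 0.68, WARS at 0.67 and YARS at 0.58, while HARS was at -0.01 ± 0.06. Genes of amino acid and one-carbon synthesis rose in 11 of 19 cases and fell in 1 (11 and 2 when adjusted over the list alone). Besides ASNS these included CTH, PSAT1 (1.51) of serine synthesis and MTHFD2 (1.16) of the mitochondrial folate pathway. The 1 that fell, ALDH18A1, was named after its values were seen. These 3 lists passed with an estimated correlation as well (adjusted p = 0.0017, 0.013 and 0.00053).

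Other lists moved in part of their members at 6 h with vehicle. XBP1 (1.97), HERPUD1 (1.48), DNAJB9 (0.96) and HSPA5 (0.49) rose among 21 endoplasmic reticulum chaperone and unfolded protein response genes (5 when adjusted over the list alone), while SYVN1 and PDIA6 were both at 0.00. That list's camera adjusted p was 0.0056, but adjusted p = 0.14 with an estimated correlation. MAPK feedback and immediate early genes rose in 6 of 27 cases (8 rose and 1 fell when adjusted over the list alone), led by ETV5 (0.98), KLF10 (0.92), KLF4 (1.07) and DUSP6 (0.83), with a camera adjusted p of 4.6e-05 and adjusted p = 0.27 with an estimated correlation. Ribosome biogenesis genes fell in 4 of 29 cases (5 when adjusted over the list alone), namely NOP2 (-0.44), POLR1C (-0.39), RRP9 (-0.46) and NOP16 (-0.33). The camera adjusted p was 0.00067, and adjusted p = 0.20 with an estimated correlation. Cholesterol synthesis genes had a median of -0.19 with 1 of 22 fallen, TMEM97 at -0.40 (1 when adjusted over the list alone). Glycolysis and hypoxia response genes had a median of -0.11 with VEGFA up at 1.26 and PFKFB3 down at -0.49 (1 and 1 when adjusted over the list alone). Both passed camera (adjusted p = 0.039 and 0.041) but neither passed with an estimated correlation (adjusted p = 0.58 and 0.60).

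The remaining lists did not pass camera at 6 h with vehicle, though single members did. BBC3 (1.55), TNFRSF10B (0.50), GDF15 (1.89), DDB2 (0.31) and 1 more of 20 p53 target genes rose, while FAS was at -0.01 ± 0.25. MAP1LC3B (1.12), GABARAPL1 (0.80), ULK1 (1.46), NBR1 (0.47) and 1 more of 26 autophagy and lysosome genes rose. PMAIP1 (1.05), BBC3 and TNFRSF10B rose among 18 apoptosis regulators, and BID fell by 0.39. IL1A (1.60) and CCL20 (2.52) rose among 17 inflammatory genes, and CCNE1 (-0.47), ORC1 (-0.28) and MCM10 (-0.32) fell among 30 DNA replication genes. CDC25C (0.43) rose among 30 mitosis genes, CDH2 (0.70) among 16 mesenchymal genes, and GRHL2 (0.31) and ESRP1 (0.48) among 16 epithelial genes. SLC7A11 rose and OSGIN1 (-0.67) fell among 20 NRF2 targets, and OAS3 (-0.33) fell among 16 interferon-stimulated genes. Adjusted over the list alone, p53 targets had 6 risen and 1 fallen, autophagy genes 5 and 0, apoptosis regulators 5 and 1, inflammatory genes 2 and 0, and DNA replication genes 0 and 3. Mitosis genes had 0 and 0 in that count, mesenchymal genes 1 and 0, epithelial genes 2 and 1, NRF2 targets 1 and 1, and interferon-stimulated genes 1 and 1. None of 51 cytosolic ribosomal protein, 14 fatty acid synthesis, 11 replication-dependent histone or 13 mitochondrially encoded genes passed. Adjusted over the list alone, the last 4 lists again had 0 genes.

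Fewer libraries, other fits and a GC correction chosen after the data were seen moved this count. The 3 libraries per group fitted alone gave 866 risen and 563 fallen genes, the GC correction gave 1083 and 744, and the fit without the 3 libraries of most negative GC slope gave 1085 and 839. That last fit left out no library of the groups compared, so its rise came through the shared fit. With 1 library left out the count was as low as 479 (vehicle with asparagine, replicate 1).

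**Figure D3:**
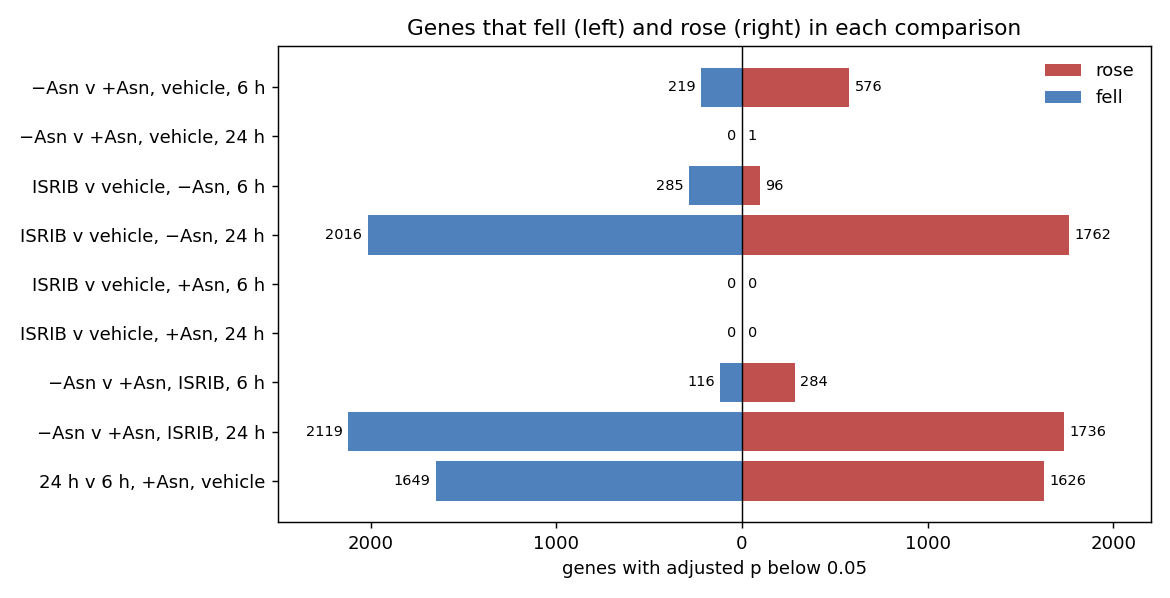
Number of genes with adjusted p below 0.05 that rose (right) and fell (left) in each comparison between 2 groups; "v" stands for versus and "veh" for vehicle. Asparagine withdrawal changed 576 plus 219 genes with vehicle at 6 h and 1 gene at 24 h.

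By 24 h the vehicle-treated cells kept a difference in 1 gene. ASNS rose from 27.2 ± 1.58 to 57.1 ± 2.40 CPM, a log2 change of 1.07 ± 0.10 (edgeR adjusted p = 8.4e-06). ATF4 was at -0.09 ± 0.10, TRIB3 at -0.11 ± 0.13, CHAC1 at -0.52 ± 0.48, SLC7A11 at 0.02 ± 0.14 and PPP1R15A at 0.29 ± 0.24, and none of them passed. DESeq2 called 3 genes, 1271 genes had an unadjusted p below 0.05 in edgeR, and the fit with no filter on low counts called 186. The 1271 are more than a share of 0.05 of the 17409 genes tested, which p alone would give where nothing changes.

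Among the lists at 24 h with vehicle, NRF2 targets had a median log2 change of -0.22 and cholesterol synthesis genes one of -0.19, with 0 of 20 and 0 of 22 genes past the threshold (0 and 0 when adjusted over the list alone). Cytosolic ribosomal protein genes were at -0.14, glycolysis and hypoxia genes at -0.14, and chaperone and unfolded protein response genes at 0.10. The 5 passed camera (adjusted p = 0.00037, 0.0049, 0.0039, 0.023 and 0.033) and none passed with an estimated correlation (adjusted p = 0.47, 0.72, 0.72, 0.73 and 0.68). Log2 changes in this comparison correlated with GC content at -0.607, and chaperones and glycolysis did not pass on GC-corrected values (adjusted p = 0.064 and 0.16). ATF4 and CHOP targets had a median of -0.01, with 0 of 33 past the threshold.

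The difference between the times was tested directly. The vehicle response to withdrawal was smaller or lower at 24 h for 179 genes and higher for 34, so that CHAC1 differed by -3.63 ± 0.60, DDIT4 by -2.88 ± 0.38, SESN2 by -2.17 ± 0.30 and ASNS by -1.45 ± 0.14 on the log2 scale. EIF5, whose reads EIF5P1 can share, differed by 1.17 ± 0.23. Of 33 ATF4 and CHOP targets 18 were lower in their response at 24 h and 0 higher (30 and 1 when adjusted over the list alone; camera adjusted p = 4.3e-49, adjusted p = 2.7e-06 with an estimated correlation). The 576 genes that rose at 6 h had a median log2 change of 0.71 there and 0.07 at 24 h, and the median SE was 0.137 at both times. The equal SE follows from the fit, which gave each gene 1 estimate of spread for all groups. The number of genes moved with the method: DESeq2 gave 98 higher and 254 lower, the GC correction 269 and 468, the groups compared alone 321 in all, and the fit without the 3 libraries of most negative GC slope 140 and 351. That last fit left out no library of the groups compared.

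The next comparison asked what ISRIB did in cells without asparagine. At 6 h the largest falls included several genes that withdrawal had raised. Both comparisons use the same vehicle libraries without asparagine, with opposite sign, so mirrored values are not independent findings. ASNS was at 26.7 ± 3.34 CPM with ISRIB against 166 ± 13.6 with vehicle (SD, n = 3), a log2 change of -2.64 ± 0.10 (edgeR adjusted p = 3.5e-13). CHAC1 (-5.27 ± 0.46), with as few as 1 count in a library, DDIT4 (-3.78 ± 0.29), ADM2 (-3.54 ± 0.29), KIF21B (-2.73) and SESN2 (-2.45) fell most on the log2 scale. LMO4 (-2.30), which encodes a transcriptional cofactor, and TRIB3 (-2.27) followed. VLDLR (-3.43), ATF3 (-1.51), DDIT3 (-1.37), STC2 (-1.28), SLC7A11 (-1.16) and ATF4 (-0.99) fell too. PPP1R15A was at 0.29 ± 0.23 and did not pass. In all, 96 genes rose and 285 fell, 3 and 120 of them at least 2-fold.

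The rises under ISRIB without asparagine at 6 h were led by SNAI2 (1.21 ± 0.17), a transcriptional repressor gene of mesenchymal transition, CD274 (1.07 ± 0.26), which encodes PD-L1, and FAM111B (1.06 ± 0.26). HAS3 (0.99), which encodes a hyaluronan synthase, ID3 (0.91), ZNF462 (0.88), RHOB (0.85) and CD83 (0.81) followed.

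Of 33 ATF4 and CHOP targets 26 fell and 7 did not pass (29 fell and 2 rose when adjusted over the list alone), with GPT2 at -1.59 and RND3 at 0.67 ± 0.22, not passed. Amino acid transporter genes fell in 9 of 16 cases (9 when adjusted over the list alone), such as SLC1A4 (-1.87) and SLC6A9 (-2.10). Aminoacyl-tRNA synthetase genes fell in 7 of 18 (10 when adjusted over the list alone), such as GARS (-1.34), AARS (-0.87) and SARS (-0.73). Amino acid and one-carbon synthesis genes fell in 11 of 19 (13 when adjusted over the list alone), such as CTH (-2.25) and PSAT1 (-1.64). Chaperone and unfolded protein response genes fell in 4 of 21 (4 when adjusted over the list alone), namely HERPUD1 (-1.99), XBP1 (-1.83), HSPA5 (-0.59) and DNAJB9 (-0.57). NRF2 targets fell in 3 of 20 (7 when adjusted over the list alone), namely SLC7A11, HMOX1 (-0.69) and AKR1C1 (-0.45). Autophagy and lysosome genes fell in 3 of 26 (4 when adjusted over the list alone), namely ULK1 (-1.64), MAP1LC3B (-0.97) and TFEB (-0.95). DNA replication genes rose in 4 of 30 (10 when adjusted over the list alone), namely CCNE1 (0.56), GINS3 (0.45), SLBP (0.39) and MCM10 (0.39). These 8 lists passed camera and also passed with an estimated correlation, the largest adjusted p being 0.017. DNA replication genes did not pass with an estimated correlation on GC-corrected values (adjusted p = 0.074).

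Ribosome biogenesis genes had a median of 0.12 with RRS1 up at 0.44 (1 of 29; 3 when adjusted over the list alone), and inflammatory genes one of 0.36 with 0 of 17 past the threshold (0 when adjusted over the list alone). Cytosolic ribosomal proteins had a median of -0.10, with 0 of 51, and glycolysis and hypoxia genes one of -0.11, with VEGFA down at -0.94 (1 of 25; 1 when adjusted over the list alone). All 4 passed camera and none passed with an estimated correlation (adjusted p = 0.099, 0.61, 0.29 and 0.52). The groups compared alone gave 9 risen and 132 fallen genes, the GC correction 453 and 600, and the fit without the 3 libraries of most negative GC slope 632 in all. Without replicate 1 of vehicle and no asparagine the count was 245.

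**Figure D4:**
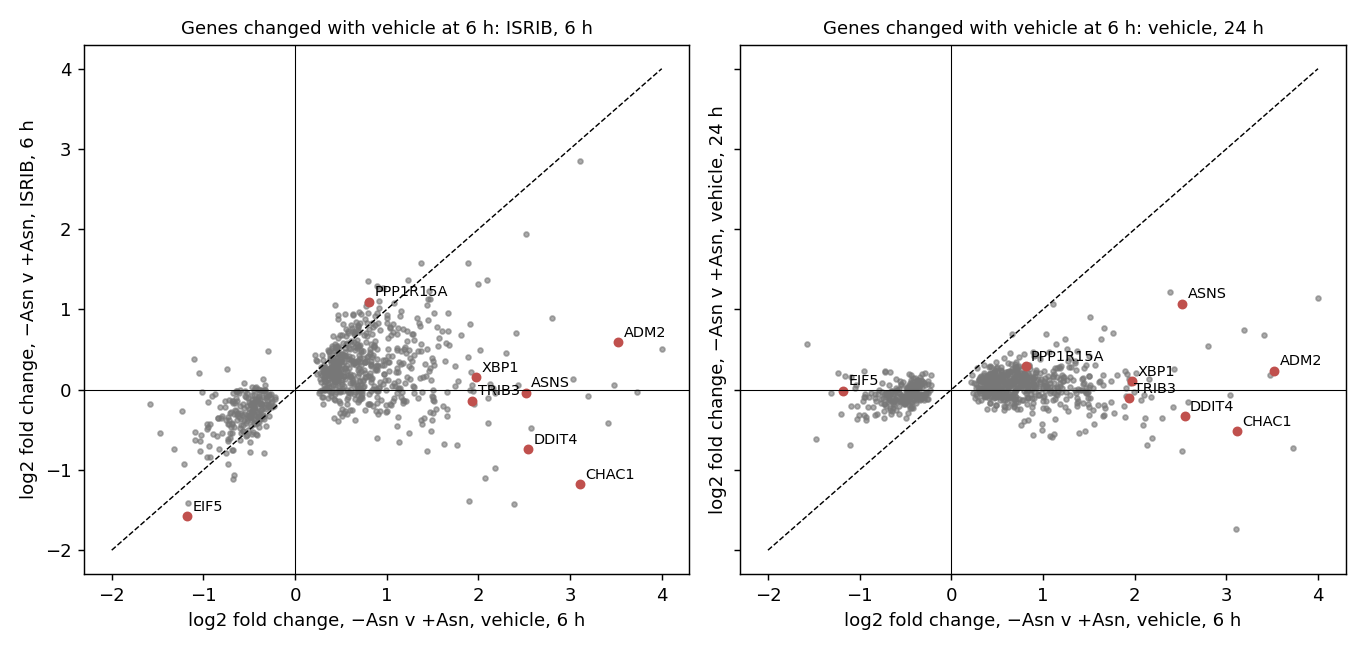
Log2 fold changes of the 795 genes that changed on asparagine withdrawal with vehicle at 6 h (horizontal axis), against the same contrast with ISRIB at 6 h (left, vertical axis) and with vehicle at 24 h (right, vertical axis); each point is a gene and the dashed line marks equal values. ASNS, at 2.52 on the horizontal axis, lies at -0.04 with ISRIB and at 1.07 at 24 h, and PPP1R15A at 1.10 with ISRIB.

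Without asparagine at 24 h, ISRIB changed far more genes than at 6 h, and other ones led. TMEM198 rose by 2.36 ± 0.27 on the log2 scale (edgeR adjusted p = 4.6e-06). VGF, which encodes a neuropeptide precursor, rose by 2.11 ± 0.31, TBCC, which encodes tubulin folding cofactor C, by 1.70 ± 0.11, RNF223 by 1.60 and SCAND1 by 1.55. The pseudogene PPIAP29 (1.52), whose reads its parent gene can share, CTU1 (1.46), which encodes a tRNA thiolase, and HSPB8 (1.41), a small heat shock protein gene, followed. EIF5 fell from 1131 ± 9.98 to 270 ± 35.3 CPM (log2 change -2.07 ± 0.17) and its pseudogene EIF5P1 was at -2.27, and AKR1B10, an aldo-keto reductase gene, fell from 617 ± 39.5 to 176 ± 5.83 CPM (-1.81 ± 0.09) with AKR1B10P1 at -1.89. Values of these 2 pairs were uncertain for shared reads. CYP4F3 (-2.02), HSD3B1 (-1.92), ASNS (-1.67 ± 0.10) and MAP2 (-1.58) fell as well. In all, 1762 genes rose and 2016 fell, 226 and 232 of them at least 2-fold. Log2 changes here correlated with GC content at 0.495. Library slopes on GC ran from -0.178 to -0.008 with vehicle and from -0.044 to 0.209 with ISRIB. After the GC correction 3289 of the changed genes passed in the same direction.

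Stress-response genes went both ways at 24 h. SLC7A11 (-1.09), STC2 (-0.82), VLDLR (-0.60) and ATF4 (-0.34) fell, while PPP1R15A rose by 0.89 ± 0.24 and DDIT3 by 0.60 ± 0.16. Of 33 ATF4 and CHOP targets 3 rose and 7 fell (4 and 8 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.17). On GC-corrected values it passed as lower (adjusted p = 0.0065), though not with an estimated correlation (adjusted p = 0.12). Aminoacyl-tRNA synthetase genes rose in 1 and fell in 4 of 18 cases (2 and 4 when adjusted over the list alone), and transporter genes rose in 2 and fell in 2 of 16 (2 and 4 when adjusted over the list alone). SLC3A2 (0.63) and SLC43A2 (1.05) rose and SLC7A2 (-1.32) fell. Amino acid and one-carbon synthesis genes rose in 1 and fell in 9 of 19 cases (3 and 10 when adjusted over the list alone), with PSAT1 at -0.87 and GOT2 at -0.31 (camera adjusted p = 0.0049, adjusted p = 0.23 with an estimated correlation).

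NRF2 targets fell in 13 of 20 cases (13 when adjusted over the list alone), with AKR1B10, AKR1C1 (-1.46), AKR1C2 (-0.99) and SLC7A11 in front and TKT at -0.02 ± 0.12. Cholesterol synthesis genes fell in 11 of 22 and rose in 2 (12 and 2 when adjusted over the list alone), with SQLE at -0.84, HMGCS1 at -0.95 and FDFT1 at -0.48. Fatty acid synthesis genes fell in 6 of 14 (6 when adjusted over the list alone), with ME1 at -0.89 and ACSL1 at -0.53. Glycolysis and hypoxia response genes fell in 9 of 25 (9 when adjusted over the list alone), with SLC2A3 at -1.12 and HK2 at -0.75. Replication-dependent histone genes rose in 5 of 11 (7 when adjusted over the list alone), with HIST1H2BK at 1.13 and HIST2H2BE at 1.11. Mitochondrially encoded genes fell in 4 of 13 (4 when adjusted over the list alone), with MT-ND4 at -0.44. Each of these 6 lists passed camera (adjusted p = 1.7e-07, 0.001, 0.0045, 0.019, 0.0025 and 0.026) and none passed with an estimated correlation (adjusted p = 0.076, 0.39, 0.39, 0.81, 0.29 and 0.81).

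The other lists did not pass camera. MCM7 (0.57), MCM2 (0.62), UHRF1 (0.45) and 6 more of 30 DNA replication genes rose and RRM1 (-0.60) fell, and TTK (-0.91), CCNA2 (-0.42), KIF23 (-0.43) and 2 more of 30 mitosis genes fell while AURKB (0.40) rose. Ribosome biogenesis genes rose in 8 and fell in 5 of 29 cases, with RRS1 at 0.80 and WDR43 at -0.64. Cytosolic ribosomal protein genes rose in 5 and fell in 4 of 51, with RPL4 at -0.76. Interferon-stimulated genes fell in 5 of 16, with OAS3 at -0.62 and MX1 at -0.97, and 0 of 17 inflammatory genes passed. KLF10 (0.99), KLF4 (1.08), JUN (1.14) and IER2 (1.17) rose and 4 of 27 MAPK feedback and immediate early genes fell. Leaving out the 3 libraries of most negative GC slope raised the count of changed genes to 6456, and leaving out replicate 1 with ISRIB and no asparagine lowered it to 2073. None of the 3 is in the groups compared here, so the 6456 came through the shared fit and does not weigh GC content.

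With asparagine present, neither time gave a gene past the threshold for ISRIB against vehicle. ASNS was at 27.4 ± 2.51 CPM with ISRIB and 29.0 ± 2.11 with vehicle at 6 h, a log2 change of -0.08 ± 0.10, and was at -0.32 ± 0.10 at 24 h (edgeR adjusted p = 0.997). CHAC1 was at -0.98 ± 0.44 and -1.64 ± 0.54, TRIB3 at -0.20 ± 0.13 and -0.05 ± 0.13, and ATF4 at 0.01 ± 0.10 and -0.01 ± 0.10. The ASNS values at 24 h did not overlap, at 20.8 to 23.7 CPM with ISRIB and 25.6 to 28.8 with vehicle. Those of ATF4 overlapped at both times, and CHAC1 had a count of 0 in replicate 3 with ISRIB at 24 h. The edgeR test counted 0 genes at each time and DESeq2 also 0. Unadjusted p in edgeR was below 0.05 for 203 and 248 genes. Both are fewer than a share of 0.05 of the 17409 genes tested, which p alone would give where nothing changes. Such a shortfall is not added evidence for no change, since p that run too high can also hide real changes. Each comparison held 1 of the 3 libraries of most negative GC slope, at -0.19 for 6 h and -0.38 for 24 h. In simulated data for these comparisons, 38 of 50 and 41 of 50 genes with a 2-fold change and 28 and 27 of 50 with a 1.5-fold change were recovered. Genes of all folds were simulated together, which eases the adjusted threshold, and without the GC trend of the libraries. A lone changed gene in the real data could thus be missed more often. Without a filter on low counts 7 and 8 genes passed.

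ATF4 and CHOP targets had medians of -0.12 at 6 h and -0.08 at 24 h with ISRIB and asparagine, and 0 of 33 passed at either time (0 when adjusted over the list alone). Chaperone and unfolded protein response genes had a median of 0.10 and mitochondrially encoded genes one of -0.15 at 24 h, with 0 of 21 and 0 of 13 past the threshold. Camera gave adjusted p = 0.011 for the stress targets at 6 h, and 0.0014 for these 3 lists at 24 h. None passed with an estimated correlation (adjusted p = 0.76 at 6 h, and 0.39, 0.28 and 0.80 at 24 h), and on GC-corrected values the 6 h call was lost (adjusted p = 0.11). Log2 changes correlated with GC content at -0.696 at 6 h and -0.577 at 24 h.

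Withdrawal was also measured in cells that had ISRIB in both media. At 6 h FILIP1L (1.58 ± 0.29), CD274 (1.51 ± 0.26), IL6 (1.38 ± 0.28), RND3 (1.36 ± 0.23) and TBCC (1.29 ± 0.12) rose most. EIF5 (-1.57) and EIF5P1 (-1.42), which can share reads, TNFRSF10D (-1.11), OSGIN1 (-1.07) and HSPA8 (-0.92), the constitutive heat shock cognate gene, fell most. ASNS was at -0.04 ± 0.10, ATF4 at -0.18 ± 0.10, TRIB3 at -0.14 ± 0.13, and CHAC1 at -1.18 ± 0.56, and none of them passed. PPP1R15A rose by 1.10 ± 0.23 (edgeR adjusted p = 0.011). In all, 284 genes rose and 116 fell, 30 and 7 of them at least 2-fold.

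Of 33 ATF4 and CHOP targets 2 rose, RND3 and PPP1R15A (3 when adjusted over the list alone), and the list did not pass camera. SLC38A2 rose by 0.51 among the 16 transporters. KLF10 (1.26), IER2 (1.17), KLF4 (0.82), KLF6 (0.96) and 2 more of 27 MAPK feedback and immediate early genes rose (9 when adjusted over the list alone), and IL6 of 17 inflammatory genes (7 when adjusted over the list alone). NRF2 targets fell in 5 of 20 cases (7 when adjusted over the list alone), among them OSGIN1, HMOX1 (-0.81), AKR1B10 (-0.41) and AKR1C2 (-0.38), and this list passed camera and passed with an estimated correlation (adjusted p = 1.8e-09 and 0.031), but not on GC-corrected values (adjusted p = 0.12 with an estimated correlation). The first 2 passed camera (adjusted p = 1.4e-08 and 2.7e-07) but not with an estimated correlation (adjusted p = 0.23 and 0.29). DNA replication genes rose in 3 of 30 (6 when adjusted over the list alone), and mesenchymal genes rose in 2, among them SNAI2 (1.22), and fell in 1 of 16, COL4A1 (-0.52), with 2 and 1 when adjusted over the list alone. Camera passed these lists as well as synthesis genes (median -0.13), glycolysis genes (-0.16) and ribosomal proteins (-0.08), with 0 genes past the threshold in the last 3. With an estimated correlation none of the 5 passed (adjusted p = 0.29, 0.53, 0.062, 0.53 and 0.53). The count of 400 depended on the fit: the 6 libraries of these groups alone gave 0 genes, DESeq2 gave 691 and the GC correction 1464, and leaving out replicate 2 with ISRIB and asparagine gave 188.

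At 24 h withdrawal with ISRIB changed 3855 genes, 1736 up and 2119 down. The comparison of ISRIB with vehicle without asparagine at 24 h uses the same ISRIB libraries without asparagine, so genes leading both are not independent findings. TMEM198 (2.39 ± 0.27), VGF (2.14 ± 0.31), TBCC (1.79 ± 0.11), RNF223 and SLC16A1-AS1 rose most. The last lies antisense to another gene, and without a stated strand its reads could not be told apart from that gene's. CYP4F3 (-2.37), EIF5P1 (-2.36) and EIF5 (-2.15), which can share reads, AKR1B10 (-2.12), with its own pseudogene, and MAN1A1 (-2.10) fell most. SLC7A11 (-1.12), DDIT4 (-0.83), STC2 (-0.71), VLDLR (-0.59) and ATF4 (-0.41) fell, PPP1R15A rose by 1.26 and DDIT3 by 0.68, and ASNS was at -0.28 ± 0.10 (adjusted p = 0.055). Cholesterol synthesis genes fell in 15 of 22 cases and rose in 1 (15 and 1 when adjusted over the list alone), with SQLE at -1.06, HMGCS1 at -1.12 and FDFT1 at -0.68. NRF2 targets fell in 13 of 20 (16 when adjusted over the list alone), with AKR1C1 at -1.74 and GSR at -0.49. Fatty acid synthesis genes fell in 7 of 14 (8 when adjusted over the list alone), with ME1 at -0.99, and glycolysis genes in 11 of 25 (12 fell and 1 rose when adjusted over the list alone), with SLC2A3 at -1.24. Histone genes rose in 3 of 11 (6 when adjusted over the list alone), with HIST1H2BJ at 1.43, and synthesis genes rose in 2 and fell in 8 of 19 (3 and 11 when adjusted over the list alone), with GOT2 at -0.37 and PSAT1 at -0.74. All 6 passed camera, and of them NRF2 targets passed with an estimated correlation (adjusted p = 0.017, and 0.070 on GC-corrected values) while the others had adjusted p = 0.24, 0.26, 0.49, 0.31 and 0.27 in the order named. The groups compared alone gave 1544 genes, the GC correction 5967 and the fit without replicate 1 with ISRIB and no asparagine 2415.

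**Figure D5:**
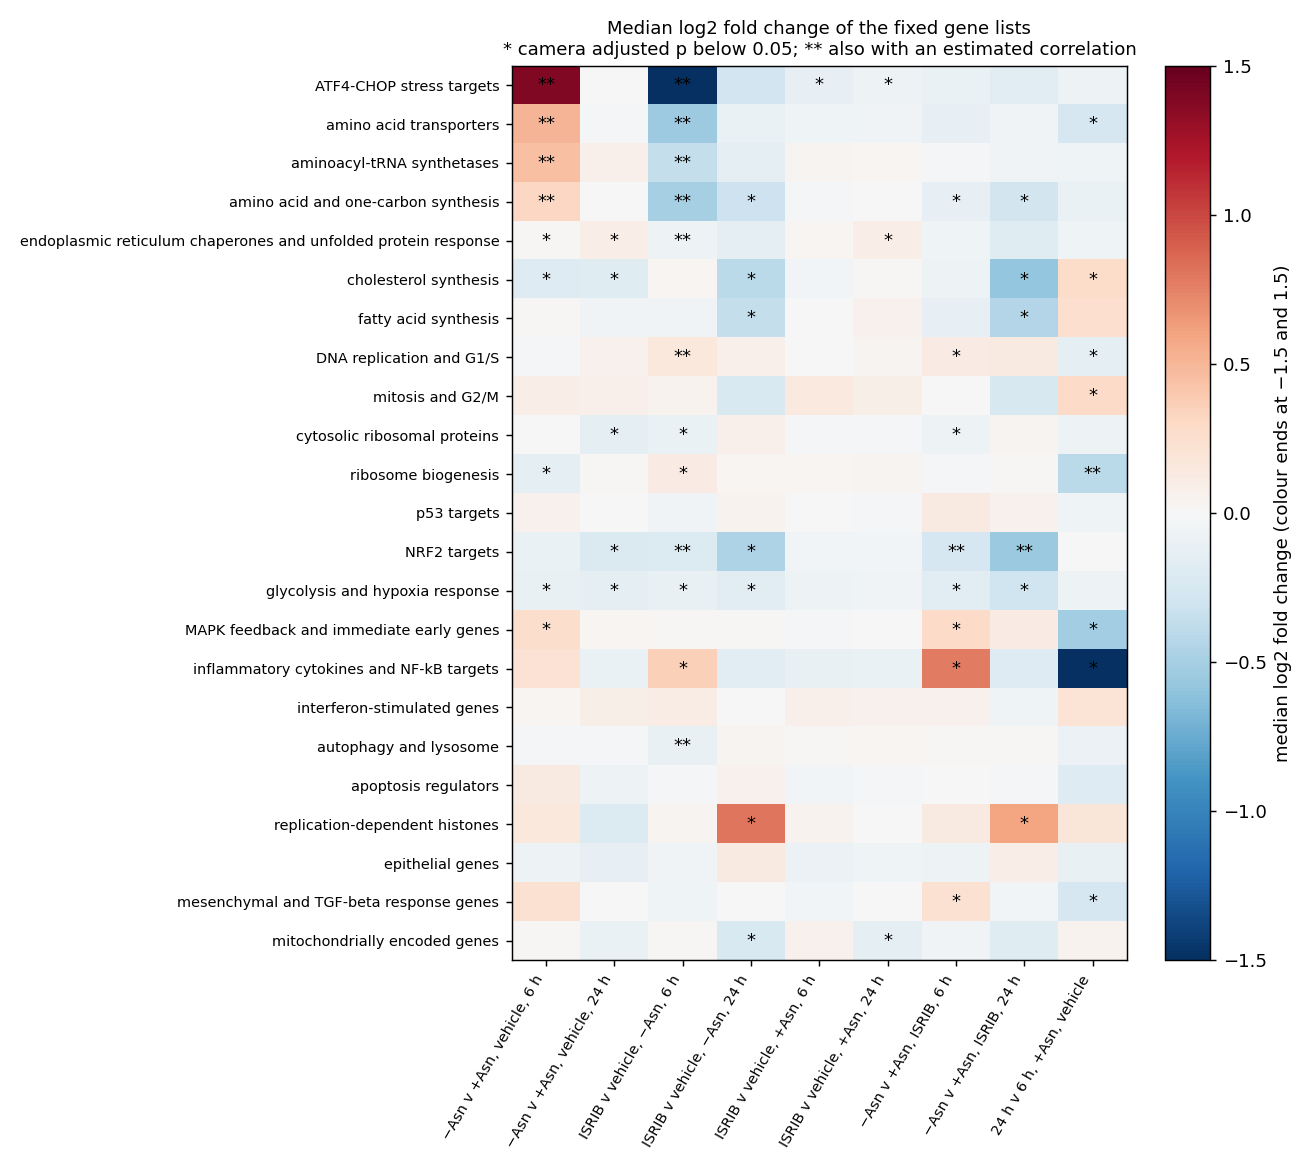
Median log2 fold change (colour, ending at -1.5 and 1.5) of 23 fixed gene lists (vertical axis) in 9 comparisons (horizontal axis); asterisks mark camera adjusted p below 0.05, and double asterisks mark lists that also passed with an estimated correlation. ATF4 and CHOP targets stand at 1.38 on withdrawal with vehicle at 6 h and -1.49 for ISRIB against vehicle without asparagine at 6 h.

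Whether the withdrawal response differed between ISRIB and vehicle was tested as an interaction. At 6 h it was lower with ISRIB for 115 genes and higher for 10. CHAC1 differed by -4.29 ± 0.66, DDIT4 by -3.29 ± 0.40, ASNS by -2.56 ± 0.14, SESN2 by -2.21 ± 0.29 and LMO4 by -2.20 ± 0.20. SNAI2 (1.26), HAS3 (0.99), ZNF462 (0.88) and FOXC1 (0.80) were higher. PPP1R15A, at 0.29 ± 0.33, did not pass. Of 33 ATF4 and CHOP targets 20 were lower and 0 higher (26 and 1 when adjusted over the list alone; adjusted p = 6.4e-07 with an estimated correlation). At 24 h 604 genes were higher and 973 lower with ISRIB. VGF (2.24), SCAND1 (1.74) and TBCC (1.74 ± 0.16) were higher, with the pseudogenes PPIAP29 (1.67) and RPS24P8 (1.64), and EIF5P1 (-2.53), TLR4 (-2.16), EIF5 (-2.14 ± 0.23), CYP4F3 (-1.97) and AKR1B10P1 (-1.96) were lower. At 6 h the GC correction gave 65 higher and 230 lower genes and the groups compared alone 72 in all, and at 24 h DESeq2 gave 2374 genes, the GC correction 3024 and no filter on low counts 2556. Leaving out 1 library lowered the 24 h count by more than 1.5 times in 7 cases, to as few as 806 without replicate 2 with vehicle and asparagine.

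The size of the response left under ISRIB was measured over the 186 genes that changed at least 2-fold with vehicle at 6 h. The slope of their log2 change with ISRIB on that with vehicle was 0.147, across genes that are not independent of each other, and the median ratio was 0.190. The slope was 0.0876 without replicate 2 of vehicle and no asparagine at 6 h and 0.0817 without the 3 libraries of most negative GC slope. The 2 contrasts shared no library, but genes chosen for a large vehicle change bias the slope towards 0. The slope with each of the 3 libraries with ISRIB and no asparagine used alone in the same model ran from 0.0343 to 0.103, with a mean of 0.0751 and an SD of 0.0361. On log2 CPM with an offset of 2 counts the mean was 0.125 and the SD 0.0114, and with an offset of 0.01 CPM 0.0837 and 0.0272, so the spread depended on how it was computed and all 3 means lay below the pooled slope. At 24 h 1 gene qualified, ASNS, with a slope of -0.259, and the 186 genes chosen at 6 h had a slope of 0.331 there. With vehicle, the changes of these 186 genes at 24 h had a slope of 0.0234 on those at 6 h. The 0.331 is thus taken on small vehicle changes and is not a share of the 6 h response. ASNS, chosen at 24 h, had -0.0158 at 6 h.

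Part of the early response was shared between ISRIB and vehicle in direction. Of the 576 genes that rose with vehicle at 6 h, 130 also rose with ISRIB, where independent lists would share 9.40, and 449 had the same sign; of the 219 that fell, 48 also fell, where 1.46 would be shared. The median log2 changes were 0.71 with vehicle and 0.24 with ISRIB for the first set and -0.51 and -0.27 for the second. With ISRIB, 167 of the 284 genes that rose at 6 h also rose at 24 h (28.3 for independent lists) and 97 of the 116 that fell also fell (14.1). These pairs of contrasts shared no library. At 6 h, however, log2 changes on withdrawal correlated with GC content at -0.466 with vehicle and -0.296 with ISRIB, which can add to their overlap. The value for independent lists is therefore not an exact base. Of the 576 genes, 328 had the same sign for ISRIB with asparagine at 24 h, where 0 genes passed.

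The ISRIB effect without asparagine differed between the times for 1322 genes, 584 higher and 738 lower at 24 h. CHAC1 differed by 4.39 ± 0.79, DDIT4 by 3.13 ± 0.40, TRIB3 by 2.56 ± 0.18, SESN2 by 2.52 ± 0.30 and TSC22D3, which encodes a glucocorticoid-induced leucine zipper, by 2.37 ± 0.32. HSD3B1 (-1.94), TLR4 (-1.73), EIF5 (-1.76) and the pseudogenes EIF5P1 (-2.19) and AKR1B10P1 (-1.74) were lower. Of 33 ATF4 and CHOP targets 20 were higher and 0 lower (24 and 0 when adjusted over the list alone; adjusted p = 0.00052 with an estimated correlation). The GC correction gave 2801 genes and no filter on low counts 1203 higher and 982 lower, and the count was as low as 674 with 1 library left out (replicate 2 of vehicle and no asparagine at 6 h).

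Vehicle-treated cells with asparagine also differed between 24 h and 6 h after the change of medium, which sets the background for the comparisons across time. CXCL8, a neutrophil chemokine gene, fell from 402 ± 160 to 11.9 ± 3.04 CPM (log2 change -5.08 ± 0.51; edgeR adjusted p = 1.3e-06). CXCL1 (-4.24), SERPINB2 (-4.21), PTGS2 (-3.83), which encodes cyclooxygenase-2, and TNFAIP3 (-3.57) fell as well. CCNG2 (2.46 ± 0.39), RBBP8NL (1.93), ZNF204P (1.74), RTN4RL1 (1.72) and KLHL24 (1.66) rose. PPP1R15A (-1.94), STC2 (-1.67), SESN2 (-1.02), ATF3 (-0.92) and ATF4 (-0.67) fell, VLDLR rose by 0.88, and ASNS was at -0.09 ± 0.10. In all, 1626 genes rose and 1649 fell, and with upper-quartile scaling 2323 rose and 1188 fell.

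Inflammatory genes fell in 15 of 17 cases between 6 and 24 h (16 when adjusted over the list alone), with ICAM1 at -2.33 and NFKBIA at -1.51, and SOD2 at -0.60 ± 0.23 did not pass. MAPK feedback and immediate early genes fell in 13 of 27 and rose in 1 (15 and 1 when adjusted over the list alone), with FOSL1 at -2.31 and DUSP5 at -1.23. Ribosome biogenesis genes fell in 17 of 29 (24 when adjusted over the list alone), with DKC1 at -0.75 and RRP12 at -0.76. Mesenchymal and TGF-beta response genes fell in 7 of 16 (7 fell and 1 rose when adjusted over the list alone), with CTGF at -2.32 and CYR61 at -1.99. Mitosis genes rose in 9 of 30 and fell in 1 (11 and 1 when adjusted over the list alone), with CDC25C at 0.79, and cholesterol synthesis genes rose in 5 of 22 and fell in 1 (7 and 1 when adjusted over the list alone), with INSIG1 at 1.49. DNA replication genes fell in 6 of 30 (6 when adjusted over the list alone), with CDC6 at -0.35, and transporter genes in 6 of 16 (7 fell and 1 rose when adjusted over the list alone), with SLC7A1 at -0.95. All 8 lists passed camera. Ribosome biogenesis passed with an estimated correlation (adjusted p = 0.030, and 0.33 on GC-corrected values), and the other 7 did not (adjusted p = 0.089, 0.21, 0.21, 0.56, 0.53, 0.40 and 0.19 in the order named). The fit without the 3 libraries of most negative GC slope gave 5203 genes and the GC correction 5476, and leaving out replicate 2 or 3 of vehicle with asparagine at 6 h gave 2109. The fit with 5203 left out no library of the groups compared.

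Markers of fibroblasts, immune cells and endothelium, which a pure line should carry at low level, were measured for 5 of 17 genes. They did not pass camera in any of the 13 comparisons. That test weighs changes between groups, not the level of the markers, so it does not bear on purity. PECAM1 differed by -1.62 ± 0.32 and COL1A1 by 0.96 ± 0.22 with ISRIB without asparagine at 24 h, and by -2.19 and 0.82 on withdrawal with ISRIB at 24 h. Between 6 and 24 h with vehicle and asparagine CDH5 fell by 2.68 and PECAM1 rose by 1.63.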

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

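The 3 tests of the weaker vehicle response at 24 h, the GC correction of the ISRIB response, the comparison of GC slopes between treatment groups and the breakdown of splits with an intact pair of groups were chosen after the result was seen. The reading of the interaction as a test of recovery and that of the GC slopes between groups were also changed to open ones after their values were seen. So was that of the SE at both times, and the weighing by the size of the log2 changes was added then.

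The vehicle response to withdrawal differed between 24 h and 6 h in 213 genes by the test of the difference itself. The response was lower at 24 h for CHAC1 (-3.63), VLDLR (-2.73), DDIT4 (-2.88), TSC22D3 (-2.65), KIF21B (-2.46), SESN2 (-2.17), TRIB3 (-2.04), DDIT3 (-1.46), ATF3 (-1.46), ASNS (-1.45), SLC7A11 (-0.98) and ATF4 (-0.91), and higher for CNNM1 (1.26), EIF5 (1.17), PPARGC1B (1.10), HSPA8P1 (1.07) and JPH1 (0.96). EIF5 and HSPA8P1 can share reads with copies elsewhere. Of 50 splits of the libraries, 4 gave as many genes with the real one included, and the highest other gave 383. Of the 49 other splits, 11 kept a real pair of groups intact and 3 of these gave as many genes, while the highest of the 38 without such a pair gave 11. Splits without such a pair mix libraries of different real groups, so the real effects enter their spread. Low counts are then likely with or without a real difference, so the 11 does not weigh chance. The 3 splits as large kept the real effect of their intact pair, so they do not weigh chance either. The splits thus left chance open.

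For the weaker vehicle response at 24 h, the median SE of the genes called at 6 h was 1.00 times as large at 24 h. This does not weigh lower sensitivity. The 24 libraries were fitted with 1 estimate of spread per gene, so SEs are nearly equal by construction. The 576 genes that rose at 6 h had a median log2 change of 0.71 there and 0.07 at 24 h. Lower sensitivity alone would leave the size, so these genes argued against it, though choosing them at 6 h inflates the 0.71. The lowest ASNS value without asparagine at 24 h was 1.90 times the highest with it, which argued against exchanged medium labels. Recovery that needs the ISRIB-sensitive response could leave a 24 h withdrawal response that differs between ISRIB and vehicle, which was found in 1577 genes. This stayed open, since a late ISRIB effect without asparagine that has no part in recovery would give such a difference too. In 50 splits 3 gave as many genes with the real one included and the highest other gave 4491. Of the 49 others 8 kept a real pair of groups intact, the 2 as large were among these, and the highest of the 41 without such a pair gave 0. Splits without such a pair mix real groups, so the 0 does not weigh chance. The 2 as large kept the real effect of their intact pair and do not weigh it either, so chance stayed open.

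The ISRIB response without asparagine differed between 24 h and 6 h in 1322 genes, again by the test of the difference. It was higher at 24 h for CHAC1 (4.39), DDIT4 (3.13), VLDLR (2.83), TRIB3 (2.56), SESN2 (2.52), TSC22D3 (2.37), DDIT3 (1.97), ATF3 (1.51), ASNS (0.98) and ATF4 (0.65), and lower for EIF5P1 (-2.19), HSD3B1 (-1.94), EIF5 (-1.76), AKR1B10P1 (-1.74) and TLR4 (-1.73). Both tests of a difference between times used the vehicle libraries without asparagine, with opposite sign, so mirrored values are not independent findings. In 50 splits 3 gave as many genes with the real one included, and the highest other gave 4517. There, 8 of the 49 others kept a real pair of groups intact and 2 of these gave as many, and the highest of the 41 others gave 0. The 41 mix real groups, so the 0 does not weigh chance. The 2 as large kept the real effect of their intact pair and do not weigh it either, so chance stayed open.

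The large ISRIB response without asparagine at 24 h was weighed against the GC trend of the libraries and against a single library. After the GC correction 87.1% of the 3778 calls passed in the same direction, which argued against the trend as the whole cause. The lowest count with 1 of the 6 libraries left out was 2073, which argued against a single library. Log2 changes correlated with GC content at 0.495 here, but more strongly where 0 or 1 gene was called by edgeR: -0.696 and -0.577 for ISRIB with asparagine at 6 and 24 h and -0.607 for withdrawal with vehicle at 24 h. The correlation was also stronger in 2 tests with many calls. It was 0.577 for the interaction at 24 h (1577 genes) and 0.545 for the ISRIB difference between times (1322 genes). A change of RNA with GC content that belongs to the treatment was not tested.

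The trend of counts with GC content was weighed against treatment and depth. The SD of the slope within groups was 1.94 times that of the group means, but this restates the spread within groups that made the pattern, so a part of the treatment in the trend stayed open. Depth stayed open too, with a Pearson r of 0.299 with total counts (permutation p = 0.154, n = 24, 100000 permutations). The Spearman rho was 0.135, and r was 0.294 without the 2 libraries farthest out, 0.334 within 6 h and 0.297 within 24 h. No biological explanation was tested.

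For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. With 1 of 10 splits as large in each case, the real counts were 795 and 1 for withdrawal with vehicle, 381 and 3778 for ISRIB without asparagine, 400 and 3855 for withdrawal with ISRIB at 6 and 24 h, and 3275 for time, and the highest other split gave 0. For ISRIB with asparagine all 10 of 10 splits gave 0 genes at both times in edgeR, as did DESeq2 for the real split. There 203 and 248 genes had an unadjusted p below 0.05 in edgeR, fewer than a share of 0.05 of those tested. This shortfall is not added evidence for no change. The withdrawal response differed between ISRIB and vehicle at 6 h in 125 genes, 7 of 50 splits gave as many with the real one included, and the highest other gave 191. Of the 49 others 11 kept a real pair of groups intact and 6 of these gave as many, and the highest of the 38 without gave 0. The 38 mix real groups, so the 0 does not weigh chance. The 6 as large kept the real effect of their intact pair and do not weigh it either, so chance stayed open.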

How the results depend on the processing

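The 3 alternatives on GC content and the 2 list tests on GC-corrected values were chosen after the result was seen. Of the values compared for the genes named, in each of the 13 comparisons, 1 gene changed sign with a call on either side: CEBPB with ISRIB without asparagine at 24 h, at 0.00 and not passed, fell to -0.47 with the GC correction and -0.48 with the GC correction and replicate block. DESeq2 left 908 such values on their side of the threshold, with 27 gained and 5 lost, and the GC correction left 870, with 56 gained and 13 lost. The groups compared alone lost 78 and gained 15, no filter lost 41 and gained 42, and the 2-fold minimum lost 252, by its construction. Single libraries left out lost 503 and gained 27, over all omissions. RLE scaling, upper-quartile scaling, limma on the deposited log2 values and the replicate block alone left each count within 1.5 times, and for the changes below the cause was not tested unless stated. Each library held at least 16737384 reads in genes, and the smallest simulated changes were mostly missed at 3 libraries per group.

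In the order withdrawal with vehicle at 6 h, ISRIB without asparagine at 6 h and 24 h, withdrawal with ISRIB at 6 h and 24 h, interaction at 6 h and 24 h, the difference of the vehicle response between times, the difference of the ISRIB response between times, and time, a 2-fold minimum left 186, 123, 458, 37, 517, 66, 355, 102, 343 and 723 genes, by its construction. Fitting the groups compared alone gave 1429 for withdrawal with vehicle at 6 h, 141 for ISRIB without asparagine at 6 h, 0 and 1544 for withdrawal with ISRIB at 6 and 24 h, 72 for the interaction at 6 h and 321 for the vehicle difference between times. DESeq2 gave 3 for withdrawal with vehicle at 24 h, 691 for withdrawal with ISRIB at 6 h, 2374 for the interaction at 24 h and 352 for the vehicle difference. No filter gave 186 for withdrawal with vehicle at 24 h, 7 and 8 for ISRIB with asparagine, 2556 for the interaction at 24 h and 2185 for the ISRIB difference.

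The GC correction gave 1827 genes for withdrawal with vehicle at 6 h, 1053 for ISRIB without asparagine at 6 h, 1464 and 5967 for withdrawal with ISRIB, 295 and 3024 for the interactions, 737 and 2801 for the differences between times and 5476 for time. It kept 772 of 795, 376 of 381, 3289 of 3778, 390 of 400 and 3618 of 3855 genes of the 5 larger comparisons of treatments. Without the 3 libraries of most negative GC slope the counts were 1924 for withdrawal with vehicle at 6 h, 632 and 6456 for ISRIB without asparagine, 491 for the vehicle difference and 5203 for time. Of these, only the comparison with 632 held any of the 3 libraries. The other counts moved through the shared fit and do not weigh GC content.

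With the GC correction and the replicate block together the counts were 2173 and 8 for withdrawal with vehicle, 1398 and 5826 for ISRIB without asparagine, 1809 and 6514 for withdrawal with ISRIB, 398 and 3635 for the interactions, 1023 and 3456 for the differences between times and 6015 for time. The replicate block alone gave 992 and 1 for withdrawal with vehicle and 486 for ISRIB without asparagine at 6 h, the comparisons whose numbers paired the libraries, 4366 for ISRIB without asparagine at 24 h, 0 and 0 for ISRIB with asparagine, 555 and 4446 for withdrawal with ISRIB, 144 and 2221 for the interactions, 269 and 1779 for the differences and 3719 for time.

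The share of the 6 h response left under ISRIB, 0.147, was 0.190 with the groups compared alone, 0.184 with the strict filter and 0.0817 without the 3 libraries of most negative GC slope. Of 24 lists in 13 comparisons, camera called 96. An estimated correlation called 30, and 21 on GC-corrected values, where NRF2 targets in withdrawal with ISRIB at both times, ribosome biogenesis in time and DNA replication with ISRIB without asparagine at 6 h were among those lost. Fry called 89 (68 shared), the replicate block 96 (94 shared), the deposited log2 values 98 (96 shared) and GC-corrected values 93 (83 shared). GC-corrected values lost 13 calls and gained 10.

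For ISRIB with asparagine the counts stayed at 0 in edgeR with 1 library left out, and DESeq2 also gave 0 with all libraries. There 203 and 248 genes had an unadjusted p below 0.05 in edgeR, fewer than a share of 0.05 of those tested. Such p can run too high and hide changes. With 1 library left out the other counts ran from 479 to 594 and stayed at 1 for withdrawal with vehicle at 6 and 24 h. They ran from 245 to 353 and 2073 to 3741 for ISRIB without asparagine. They ran from 188 to 444 and 2415 to 3852 for withdrawal with ISRIB, 92 to 149 and 806 to 2235 for the interactions, 155 to 180 and 674 to 1686 for the differences between times, 2109 to 2811 for time and 0.0876 to 0.165 for the share. Fewer libraries lower these counts in part by construction.

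Libraries whose omission moved a count by more than 1.5 times follow, written as medium, drug and replicate. Withdrawal with vehicle at 6 h gave 479 and 523 without +Asn vehicle 1 and 2, and 494 and 505 without -Asn vehicle 2 and 3. ISRIB without asparagine gave 245 at 6 h without -Asn vehicle 1, and at 24 h 2300 and 2217 without -Asn vehicle 1 and 3 and 2073 and 2281 without -Asn ISRIB 1 and 3. Withdrawal with ISRIB gave 188 and 231 at 6 h without +Asn ISRIB 2 and 3, 218 without -Asn ISRIB 3, and 2415 at 24 h without -Asn ISRIB 1. The interaction at 24 h gave 806 and 871 without +Asn vehicle 2 and 3, 880 without +Asn ISRIB 3, 906 and 855 without -Asn vehicle 1 and 3, and 829 and 840 without -Asn ISRIB 1 and 3. The ISRIB difference between times gave 739 and 674 without 6 h -Asn vehicle 1 and 2, 729 without 6 h -Asn ISRIB 3, 727 and 693 without 24 h -Asn vehicle 1 and 3, and 688 and 717 without 24 h -Asn ISRIB 1 and 3. Time gave 2109 and 2109 without 6 h +Asn vehicle 2 and 3 and 2136 without 24 h +Asn vehicle 3. The share was 0.0876 without 6 h -Asn vehicle 2, and, moved by less than 1.5 times, 0.109 without 6 h +Asn vehicle 1.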

Other observations

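The test on single-exon genes was chosen after the result was seen, the adjustment for hydrophobic residues was added after the rank of asparagine was known, and the other tests in this part were planned. All log2 changes in this part are those after the GC correction, which was itself chosen after the data were seen.

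Codons for asparagine were examined in the coding sequences of 11443 genes. A hypothesis was that mRNAs rich in asparagine codons fall when asparagine is withdrawn under ISRIB. At 24 h the partial rank correlation of asparagine content with the GC-corrected log2 change was -0.155, adjusted for GC content and length of the coding sequence. It ranked 1 of 20 amino acids from the most negative, ahead of isoleucine (-0.127), phenylalanine (-0.0825) and tyrosine (-0.0794). After further adjustment for hydrophobic residues it was -0.149, which argued against their content as the whole cause. Other features of membrane or secreted proteins were not adjusted for and stayed open. Genes in 5 equal bins of asparagine content, with means of 1.54%, 2.68%, 3.44%, 4.20% and 5.55%, had median log2 changes of 0.09, 0.05, -0.00, -0.04 and -0.06, and with vehicle at 24 h -0.00, 0.00, -0.00, -0.00 and -0.00. The differences were small beside those of single genes, and a link through protein synthesis was not tested.

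Across 9 comparisons of 2 groups the correlation with asparagine content was also lowest of 20 for ISRIB without asparagine at 24 h (-0.146), which shares libraries with the former. It ranked 2 for withdrawal with ISRIB at 6 h (-0.106) and 3 for ISRIB without asparagine at 6 h (-0.0677). In the others the ranks were 7 and 10 for withdrawal with vehicle at 6 and 24 h (-0.0516 and -0.0600), 14 and 14 for ISRIB with asparagine (-0.0188 and -0.0105) and 7 for time (-0.00619).

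Genes with a single exon moved up on withdrawal with ISRIB at 24 h, and TBCC and RRS1 are among the genes that rose. Their median GC-corrected log2 change was 0.12 over 179 genes. Of 10000 lists matched to them on expression and GC content, 9995 had a lower median, the median of these lists being 0.00. The medians below are GC-corrected as well. Without histones the median was 0.09 over 170 genes. At 6 h with ISRIB the median was 0.09 and all 10000 lists were lower. With vehicle it was 0.03 at 6 h, where 9956 lists were lower but the median without histones was 0.00, and -0.01 at 24 h, where 2569 were lower. What single-exon genes have in common here, such as a lack of splicing or short length, was not separated.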
